A study of Danio rerio with 6 samples.

How the data were processed

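RNA was measured in GFP+ cells of Tg(fli1a:eGFP) zebrafish embryos at 28 hours post fertilization. This transgene drives green fluorescent protein from regulatory sequence of fli1a, which is active in endothelium and, as background knowledge, in some blood and pharyngeal arch cells. Embryos carried either a control morpholino (MO) or a clec16a MO; a morpholino is an antisense oligomer that blocks splicing or translation of its target. The labels do not say which of these the clec16a MO does. There were 6 libraries, 3 per group. Groups were taken from the genotype label. The titles, which begin with Exp2D for the control MO and NegaP for the clec16a MO samples, do not name the morpholino. The labels call both groups GFP+ cells and do not say how the cells were gated. Nothing in the labels says that replicates came from separate clutches, so p-values measure only the spread between these samples, which may be technical. No batch, day or lane is given, so a batch that followed the groups and the groups themselves cannot be told apart.

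Per the labels' protocols, cDNA was made from small amounts of total RNA with an oligo(dT) primer and template switching (SMARTer), amplified by PCR, fragmented and sequenced in paired ends. The authors deposited one table of FPKM values (fragment numbers scaled by transcript length and by the mapped fragments of the library), with one column per library. Cutadapt 1.9, HISAT2 2.2.1 and StringTie 2.1.6 are named in the submitters' processing notes, without their settings. The genome build and annotation are not given in the sources used here, so no coordinates are printed. FPKM values are relative: a gene that takes a larger share of a library lowers the values of the rest.

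The table had 21853 rows. Of these, 16 carried a calendar date in place of a gene name and were left out of the tests. Of the 21837 remaining, 503 repeated a name already used, and 400 names had more than 1 row. Such rows were kept apart and count as uncertain, since the sources used here do not say how reads were divided between them. The names of 17926 rows (82.1%) were symbols in the reference gene tables, which belong to assembly GRCz12tu and were used for names only.

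Depth is unknown, because FPKM values carry no totals. The low values were searched for steps of whole reads, among genes below 1 FPKM in the first library of a pair. Genes were counted whose ratio between the libraries lay within 0.08% of a given ratio, or of a doubling above or below it. In the 3 pairs of control libraries, 53, 43 and 36 genes were counted in this way at the commonest ratio, against a median of 11 genes per ratio. In the 3 pairs of clec16a MO libraries it was 16, 19 and 16 genes, against a median of 6, and no relative depth was taken from them. An exact 0 in the table can be a failed estimate: nup54, a nuclear pore protein used by every cell and singled out after its values were seen, was listed at 0 in each clec16a MO library. Genes at 0 are therefore called listed at 0, with each library's value and no fold.

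Values were tested as log2(FPKM + 1) for the 12153 genes with a mean of at least 1 FPKM over the 6 libraries. A log2 difference on this scale understates the change of low genes. The test was limma's moderated test with a mean-variance trend (limma 3.58.1, R 4.3.3), two-sided, with group as the only term and Benjamini-Hochberg adjustment over all genes tested; the threshold was an adjusted p below 0.05. Gene lists with at least 4 measured members were tested with limma's camera, which compares a list with all other genes, at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. The same was run with a correlation estimated for each list. That run also uses fewer degrees of freedom, those left by the 6 libraries, so a call can end there without correlation between genes. Shares of a library were compared with an exact permutation test (SciPy 1.17.1), for which 3 against 3 libraries cannot give a p below 0.1. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).

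The groups, the tests, the threshold, 30 gene lists, the rule for named genes and most of the other settings were fixed before the data were examined. Of the lists, 28 could be tested; the heart muscle list had 0 measured members and the hatching gland list 2. The results of one tested list and of one gene of interest are not reported here. The rule named clec16a; the 10 largest differences in each direction among genes past the threshold whose groups did not overlap, with at least 5 FPKM in the higher group and a gene symbol; up to 4 members of each list with the smallest adjusted p; and 20 genes of interest, whatever their p. Chosen after seeing the data were 12 more lists, which include 7 protein complexes, and 2 settings: leaving out embryonic globin, mitochondrial protein and ribosomal protein genes with each library rescaled, and summing rows of one name. The settings fixed in advance were a pseudocount of 0.1, no filter, a filter at 5 FPKM, quantile normalization, median centring, no variance trend, array weights, a replicate block, an added log2 difference of 1, an estimated correlation, and leaving out each library in turn.

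The method was tested on simulated data made from the means and the spreads per group of the 12153 genes, with 200 genes changed. It recovered 68% of genes changed by 1 and 95% of those changed by 2 on the log2 scale. The changed genes were drawn only from those at higher levels, so recovery of genes near the filter of 1 FPKM was not measured. Of 186 calls, 23 (12.4%) were false, above the nominal 5%. In this 1 run, made with the groups' own unequal spreads, the threshold thus let through more false calls than its nominal share. Whether the unequal spreads caused this was not tested. The changed list, whose members were all raised, was called, and 0 of 20 unchanged lists were. The simulated genes varied independently and few of them were changed, so this does not check the list test on correlated genes.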

Results

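Expression was measured in GFP+ cells of Tg(fli1a:eGFP) zebrafish embryos at 28 hours post fertilization, in 3 control MO and 3 clec16a MO libraries. The series asks how clec16a, which encodes a membrane-associated endolysosomal protein, acts in definitive hematopoietic stem and progenitor cells (HSPCs), and its title names mitophagy. The values are deposited FPKM, whose depth is unknown. Of 21837 rows, 19284 ± 33.5 (SD, n = 3) were above 0 in the control libraries and 15580 ± 378 in the clec16a MO libraries (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 can give).

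The targeted gene was lower in the clec16a MO libraries. clec16a stood at 14.3 ± 0.144 FPKM (SD, n = 3) in the control libraries and at 5.16 ± 0.798 FPKM in the clec16a MO libraries, a log2 difference of -1.32 (SE 0.13, limma adjusted p = 5.5e-05, Benjamini-Hochberg). The 3 control libraries read 14.4, 14.1 and 14.3 FPKM, and the 3 clec16a MO libraries 5.68, 5.57 and 4.24 FPKM. With each library centred on its median the difference was -0.63, still past the threshold (limma adjusted p = 0.0031). A morpholino that blocks translation need not lower its target's mRNA, so this value alone does not check the labels. A fall of about this size was also common: 5018 of the 12153 tested genes were called lower by a log2 difference of at least 1.

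In the clec16a MO libraries, genes of red blood cells and of macrophages and neutrophils were higher, while genes of endothelium, skeletal muscle, epidermis and the ribosome were lower. These 6 lists were called by camera with its preset correlation (adjusted p from 2.8e-15 to 0.0012) and none with an estimated correlation (adjusted p = 0.10, 0.085, 0.10, 0.24, 0.15 and 0.68 with an estimated correlation, in the order named). The carbonic anhydrase gene cahz rose from 6.77 ± 1.05 to 2682 ± 128 FPKM (SD, n = 3), and the lysozyme gene lyz from 1.35 ± 0.931 to 690 ± 209 FPKM. The muscle actin gene actc1b fell from 1628 ± 5.23 to 3.23 ± 1.07 FPKM, and the endothelial transcription factor gene ets1 from 294 ± 9.52 FPKM to 1.29, 0 and 0.269 FPKM in the 3 clec16a MO libraries. Embryonic globins took 0.463% ± 0.0209 of the summed FPKM in the control libraries and 6.24% ± 1.82 in the clec16a MO libraries, and ribosomal protein genes 6.54% ± 0.27 and 0.829% ± 0.234 (exact permutation p = 0.1 for each, the smallest possible).

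Of 12153 genes tested, limma with Benjamini-Hochberg adjustment called 9877 (81.3%), 3239 higher and 6638 lower (32.8% and 67.2% of calls). The balance between the directions depended on scaling. The median log2 difference over all tested genes was -0.66, and median centring moved it by 0.69 and quantile normalization by 0.62. The counts were then 4819 higher and 4632 lower (51% and 49%) with median centring, and 4614 higher and 4835 lower (48.8% and 51.2%) with quantile normalization. A log2 difference of at least 1 was reached by 2178 of the higher and 5018 of the lower genes. The 3 libraries of one group all lay above those of the other for 10173 genes (83.7%), where chance gives 10%. Pearson's r across genes, which are not independent replicates, was 0.995 to 0.996 between control libraries, 0.970 to 0.977 between clec16a MO libraries and 0.618 to 0.639 between the groups.

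**Figure D1:**
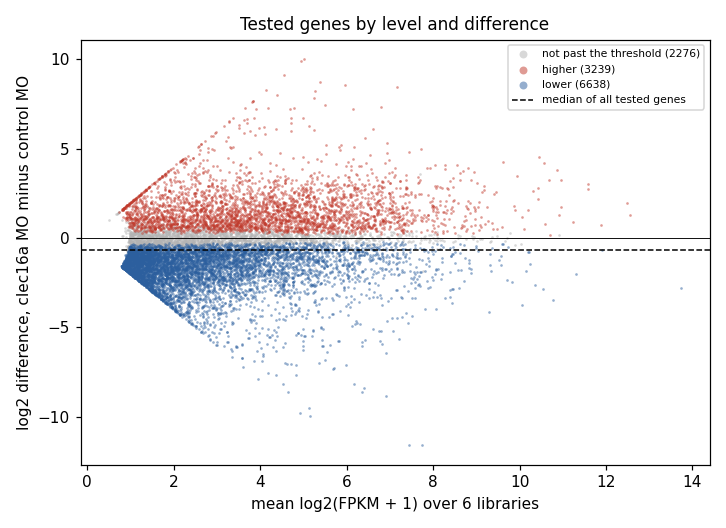
Each point is 1 of the 12153 tested genes, with its mean log2(FPKM + 1) over the 6 libraries on the x axis and its log2 difference, clec16a MO minus control MO, on the y axis; the dashed line is the median difference of -0.66. The 6638 lower genes (blue) outnumber the 3239 higher genes (red), and with median centring the counts are 4632 and 4819.

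Among the 10 largest increases of genes with a symbol and at least 5 FPKM were genes of blood cells. hemgn, a nuclear protein of erythroid cells, rose from 1.51 ± 0.144 to 580 ± 33.2 FPKM, and the biliverdin reductase gene blvrb from 7.83 ± 0.103 to 1403 ± 87.7 FPKM. hdr rose from 1.03 ± 0.168 to 856 ± 68.9 FPKM and the N-myristoyltransferase gene nmt1b from 2.40 ± 0.189 to 601 ± 107 FPKM. lect2l was listed at 0 in each control library and stood at 201, 221 and 191 FPKM in the clec16a MO libraries. 3 rows of the macrophage gene mfap4 were also listed at 0 in each control library, with 1229, 913 and 1007 FPKM for the first in the clec16a MO libraries; because rows of this name may share reads, their separate values are uncertain. The 10 largest decreases included 2 ribosomal protein genes and genes of vessels. rpl26 fell from 1230 ± 81.8 FPKM to 11.1, 5.18 and 0 FPKM and rplp2l from 741 ± 56.1 to 4.36 ± 0.315 FPKM. The homeobox gene hhex fell from 391.8 ± 13.04 FPKM to 0.662, 0.508 and 0 FPKM and igfbp7, which encodes a secreted vascular protein, from 237 ± 4.63 FPKM to 0.0134, 0 and 0 FPKM. The proteasome subunit gene psmd3 fell from 330 ± 7.40 to 1.47 ± 0.754 FPKM, rab11fip1b from 285 ± 17.1 to 1.17 ± 0.441 FPKM and the phosphatase gene ppp1cbl from 246 ± 7.36 FPKM to 1.25, 0 and 0 FPKM. Those of both sets that were not listed at 0 in one group had limma adjusted p-values (Benjamini-Hochberg) of 6.0e-05 or less.

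Endothelial genes fell, and fli1a itself, whose regulatory sequence drives the GFP, was among them. fli1a went from 1049 ± 71.2 to 107 ± 9.02 FPKM (SD, n = 3; log2 difference -3.29, SE 0.10). The VEGF receptor gene kdrl went from 80.8 ± 1.68 to 19.1 ± 2.05 FPKM, the VE-cadherin gene cdh5 from 142 ± 0.917 to 36.0 ± 7.55 FPKM and the angiopoietin receptor gene tek from 157 ± 5.30 to 0.333 ± 0.129 FPKM. erg read 141, 144 and 155 FPKM in the control libraries and was listed at 0 in each clec16a MO library. Of 24 measured endothelial genes, 1 rose, 21 fell and 2 did not pass, with the same counts adjusted over the list alone. The list ranked lower than other genes with camera (adjusted p = 0.00029), but was not called with an estimated correlation (adjusted p = 0.10 with an estimated correlation). The correlation estimated for it was -0.0086, below the preset 0.01, so correlation between its genes did not end the call. In this list 4 rose and 19 fell with median centring. etv2, an early regulator of endothelium and blood, read 476 ± 5.48 and 366 ± 54.8 FPKM; its call (log2 difference -0.39, limma adjusted p = 0.016, Benjamini-Hochberg) turned to 0.31 with median centring and was -0.60 with quantile normalization (limma adjusted p = 0.00098). It also missed the threshold without control replicate 1, 2 or 3 (limma adjusted p = 0.055, 0.051 and 0.056).

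Arterial genes fell, and so did venous genes. The arterial ligand genes efnb2a and dll4 went from 35.3 ± 0.157 to 5.69 ± 2.06 FPKM and from 29.6 ± 0.955 to 7.26 ± 2.65 FPKM, and the receptor gene notch1b from 8.40 ± 0.405 FPKM to 0, 0.0788 and 0.0897 FPKM. The venous receptor gene ephb4a went from 32.6 ± 1.72 to 0.261 ± 0.0446 FPKM and the scavenger receptor gene stab2 from 162 ± 0.328 to 22.4 ± 1.27 FPKM. Of 17 arterial genes, 0 rose, 16 fell and 1 did not pass (camera adjusted p = 0.0020; adjusted p = 0.14 with an estimated correlation). Of 11 venous and lymphatic genes, 1 rose and 10 fell (camera adjusted p = 0.0065; adjusted p = 0.15 with an estimated correlation). Of 22 Notch pathway genes, 0 rose, 20 fell and 2 did not pass (camera adjusted p = 0.0095; adjusted p = 0.26 with an estimated correlation); notch1a went from 19.5 ± 0.156 to 2.99 ± 0.627 FPKM. Of 24 genes of VEGF, BMP and Hedgehog signalling, 0 rose, 22 fell and 2 did not pass (camera adjusted p = 0.0031; adjusted p = 0.23 with an estimated correlation), such as smo, from 27.9 ± 1.35 to 2.76 ± 0.253 FPKM. Adjusted over the list alone, these counts were the same, and with median centring 1, 1, 2 and 0 genes rose and 13, 10, 15 and 16 fell. The lists are not independent. The Notch list shares dll4, dlc, hey1, hey2, notch1b and notch3 with the arterial list. The list of VEGF, BMP and Hedgehog signalling shares kdr, kdrl, flt1, nrp1a and nrp1b with the endothelial and arterial lists.

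Blood cell genes rose beside the fall of the endothelial genes. The anion exchanger gene slc4a1a went from 3.01 ± 0.385 to 311 ± 36.1 FPKM and nt5c2l1 from 0.425 ± 0.105 to 147 ± 9.999 FPKM. Of 27 measured primitive erythroid genes, 27 rose, with a median log2 difference of 4.21 (camera adjusted p = 2.8e-15; adjusted p = 0.10 with an estimated correlation). The neutrophil peroxidase gene mpx was listed at 0 in each control library and read 21.1, 18.7 and 20.1 FPKM in the clec16a MO libraries. npsn, a neutrophil protease gene, went from 2.26 ± 0.191 to 210.7 ± 18.3 FPKM, and fcer1gl, a receptor signalling subunit, from 0.271 ± 0.190 to 102 ± 7.04 FPKM. Of 25 primitive myeloid genes, 22 rose, 2 fell and 1 did not pass, with a median of 2.74 (camera adjusted p = 1.2e-09; adjusted p = 0.085 with an estimated correlation). Adjusted over the list alone, both counts were the same, and with median centring 27 erythroid and 23 myeloid genes rose.

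**Figure D2:**
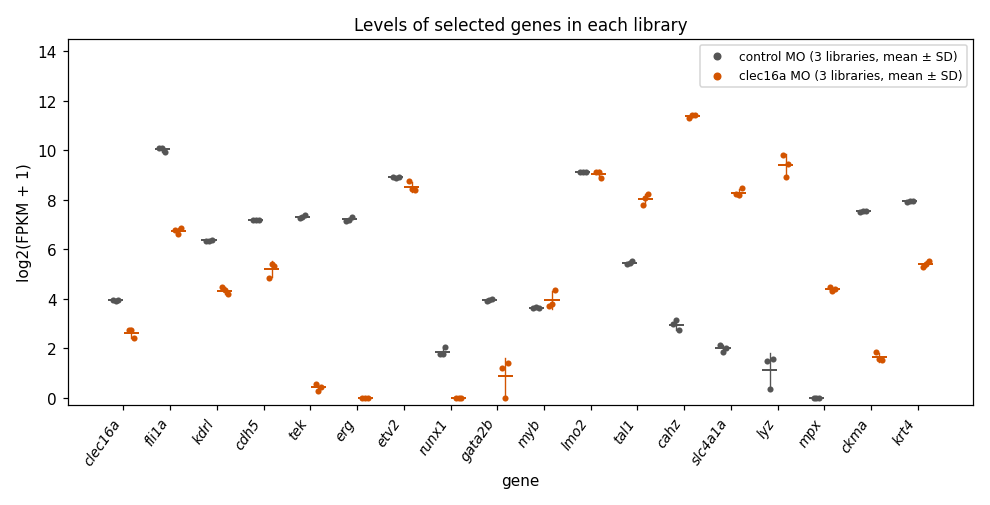
Each point is 1 library's log2(FPKM + 1) for the gene on the x axis, control MO in grey and clec16a MO in orange, with the mean and SD of 3 libraries as lines. clec16a, fli1a, kdrl, cdh5, ckma and krt4 sit lower in the clec16a MO libraries and cahz, slc4a1a, lyz and tal1 higher, while lmo2 (553 and 528 FPKM) overlaps and its direction depends on scaling.

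Genes of definitive HSPCs and hemogenic endothelium did not move as one group. runx1, which is required for HSPCs to emerge from hemogenic endothelium, read 2.40, 2.42 and 3.12 FPKM in the control libraries and was listed at 0 in each clec16a MO library. gata2b, which acts upstream of runx1, fell from 14.4 ± 0.541 FPKM to 1.29, 0 and 1.63 FPKM in the clec16a MO libraries (log2 difference -3.08, SE 0.35, limma adjusted p = 0.00012, Benjamini-Hochberg), and gata2a from 35.2 ± 1.42 to 3.94 ± 0.0523 FPKM. The blood regulator gene tal1 rose from 42.5 ± 1.84 to 260 ± 40.2 FPKM and gfi1b, an erythroid and megakaryocyte factor, from 0.504 ± 0.273 to 23.5 ± 3.01 FPKM. myb, a marker of HSPCs, read 11.5 ± 0.277 and 14.8 ± 4.19 FPKM (log2 difference 0.31, limma adjusted p = 0.16), with 12.1, 12.6 and 19.6 FPKM in the 3 clec16a MO libraries, and its difference was 0.10 without clec16a MO replicate 3 (limma adjusted p = 0.34). It passed with median centring (log2 difference 0.999, limma adjusted p = 0.0017), quantile normalization (0.72, limma adjusted p = 0.0043) and array weights (0.42, limma adjusted p = 0.035). lmo2 read 553 ± 2.63 and 528 ± 48.1 FPKM (log2 difference -0.07, limma adjusted p = 0.48) and was called in opposite directions by the scalings, at 0.62 with median centring (limma adjusted p = 0.00054) and -0.29 with quantile normalization (limma adjusted p = 0.030). Without clec16a MO replicate 3 the lmo2 difference was 0.0059. itga2b, an HSPC and thrombocyte surface gene, was below the filter, listed at 0 in each control library and at 0.228, 0.666 and 0 FPKM in the clec16a MO libraries. Of 15 measured genes, 2 rose, 10 fell and 3 did not pass, with the same counts adjusted over the list alone, and the list was not called (camera adjusted p = 0.50). With median centring 5 rose and 8 fell.

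Autophagy and mitophagy genes moved in both directions. The ubiquitin-like autophagy genes gabarapb and map1lc3b rose from 509 ± 11.3 to 3173 ± 285 FPKM and from 278 ± 2.11 to 651 ± 35.8 FPKM, and the conjugation enzyme gene atg3 from 68.9 ± 1.06 to 226 ± 19.9 FPKM. The cargo receptor gene sqstm1 fell from 40.8 ± 1.02 to 9.999 ± 1.22 FPKM. The mitophagy receptor gene fundc1 rose from 20.04 ± 0.619 to 87.8 ± 8.63 FPKM, while the outer membrane channel gene vdac3 fell from 235 ± 1.63 to 15.95 ± 1.66 FPKM. rnf41, whose product is a ubiquitin ligase that binds Clec16a, fell from 3.86 ± 0.0976 to 1.61 ± 0.527 FPKM (log2 difference -0.91, limma adjusted p = 0.0013), a call that ended with median centring (-0.22, limma adjusted p = 0.25) and quantile normalization (-0.03, limma adjusted p = 0.88). pink1 and prkn, the kinase and ligase that mark damaged mitochondria, were below the filter: pink1 read 1.46, 1.79 and 1.53 FPKM in the control libraries and 0, 0 and 0.0468 FPKM in the clec16a MO libraries, and prkn 0.256, 0.380 and 0.357 FPKM and 0.0914, 0 and 0 FPKM. Of 31 core autophagy genes, 8 rose, 20 fell and 3 did not pass (camera adjusted p = 0.90), and of 33 mitophagy genes 7 rose, 18 fell and 8 did not pass (camera adjusted p = 0.81). With median centring these counts were 12 higher and 13 lower, and 13 higher and 11 lower.

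Lysosomal and endosomal lists were not called either. The cathepsin gene ctsla fell from 1030 ± 5.14 to 146 ± 19.0 FPKM and naga, a lysosomal glycosidase gene, from 54.4 ± 1.099 to 3.82 ± 0.379 FPKM. Of 50 lysosomal genes, 10 rose, 29 fell and 11 did not pass (camera adjusted p = 0.64). In the endosome fusion and HOPS list of 30 genes, 4 rose, 17 fell and 9 did not pass (camera adjusted p = 0.64); the recycling gene rab11bb fell from 615 ± 21.3 to 88.8 ± 3.40 FPKM and ccz1, which acts in endosome maturation, rose from 37.7 ± 1.40 to 120 ± 12.1 FPKM. With median centring the counts were 20 higher and 21 lower, and 12 higher and 11 lower. Adjusted over the list alone, the counts of the autophagy, mitophagy, lysosomal and endosomal lists were the same as over all genes.

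Mitochondrial genes were mixed. Cytochrome b, mt-cyb, rose from 1190 ± 17 to 7996 ± 911 FPKM and mt-nd1 from 166 ± 9.01 to 585 ± 97.9 FPKM, while mt-nd4l fell from 303 ± 17.2 to 31.4 ± 11.1 FPKM. The protein genes of the mitochondrial genome took 2.67% ± 0.0300 of the summed FPKM in the control libraries and 5.30% ± 0.755 in the clec16a MO libraries (exact permutation p = 0.1, the smallest possible). Of 13 genes of the mitochondrial genome, 4 rose, 4 fell and 5 did not pass (camera adjusted p = 0.32). Of 87 nuclear genes of oxidative phosphorylation, 23 rose, 50 fell and 14 did not pass (camera adjusted p = 0.78, 0.0066 with quantile normalization, and 0.93 with an estimated correlation). The ATP synthase gene atp5fa1 fell from 202.0 ± 0.471 to 3.67 ± 0.577 FPKM. Of 21 genes of mitochondrial dynamics and biogenesis, 3 rose, 7 fell and 11 did not pass (camera adjusted p = 0.75, ranked upward while the median was -0.16). The mitochondrial DNA packaging gene tfam rose from 41.8 ± 2.60 to 154 ± 24.0 FPKM and the fusion gene mfn1b fell from 11.8 ± 1.28 to 2.42 ± 0.426 FPKM. Of 23 glycolysis genes, 2 rose, 17 fell and 4 did not pass (camera adjusted p = 0.051). The camera adjusted p of this list lay between 0.018 and 0.071 over 16 alternatives, and was 0.43 with an estimated correlation. The fallen muscle isoforms pgam2 and eno3 went from 28.7 ± 1.05 to 0.150 ± 0.0992 FPKM and from 40.6 ± 1.47 to 1.05 ± 0.328 FPKM. Adjusted over the list alone, these counts were the same. With median centring the oxidative phosphorylation genes counted 33 higher and 37 lower, and the glycolysis genes 5 higher and 12 lower. The balance of mitochondrial dynamics and biogenesis turned with scaling, to 13 higher and 5 lower with median centring and 12 and 4 with quantile normalization, and that of the mitochondrial genome was 9 higher and 2 lower with median centring and 3 and 6 with quantile normalization.

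Genes of the cell cycle moved in both directions. Of 44 cell cycle genes, 20 rose, 17 fell and 7 did not pass, the same adjusted over the list alone, with replication genes on both sides. gins2 rose from 26.6 ± 1.71 to 518 ± 113 FPKM and gins1 from 16.2 ± 0.827 to 166 ± 16.7 FPKM, while mcm7 fell from 45.6 ± 1.32 to 0.0437 ± 0.0410 FPKM. With median centring 26 cell cycle genes rose and 9 fell, and with quantile normalization 21 and 15. The cell cycle list ranked higher (camera adjusted p = 0.035; adjusted p = 0.65 with an estimated correlation), a call that ended with quantile normalization (camera adjusted p = 0.29) and with a filter at 5 FPKM (camera adjusted p = 0.16). cdkn1a, a gene outside this list that encodes an inhibitor of cyclin-dependent kinases, read 1.86 ± 0.217 and 3.60 ± 1.89 FPKM (log2 difference 0.60, limma adjusted p = 0.088, Benjamini-Hochberg), with 3.26, 1.89 and 5.64 FPKM in the 3 clec16a MO libraries. Its difference was 0.30 without clec16a MO replicate 3 (limma adjusted p = 0.20) and 0.90 without replicate 2 (limma adjusted p = 0.0081). It passed with median centring (1.3, limma adjusted p = 0.0040), quantile normalization (1.53, limma adjusted p = 0.00069) and array weights (0.73, limma adjusted p = 0.022).

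The stress and immune lists were not called. Of 29 genes of the mitochondrial and integrated stress response, 9 rose, 18 fell and 2 did not pass (camera adjusted p = 0.81); the transcription factor gene atf4a fell from 89.1 ± 3.16 to 6.31 ± 0.776 FPKM and the folate enzyme gene mthfd2 rose from 5.26 ± 0.443 to 47.0 ± 10.01 FPKM. Of 27 antioxidant genes, 11 rose, 12 fell and 4 did not pass (camera adjusted p = 0.19, with a median of 0.04 and a mean of -0.05); the peroxiredoxin gene prdx2 rose from 106 ± 6.81 to 770.4 ± 120 FPKM. Of 17 interferon and inflammation genes, 6 rose, 7 fell and 4 did not pass (camera adjusted p = 0.51, ranked upward while the median was -0.19); isg20 rose from 16.8 ± 0.488 to 80.9 ± 6.56 FPKM. Of 34 immediate early and heat shock genes, 7 rose, 21 fell and 6 did not pass (camera adjusted p = 0.79); the immediate early gene fosab rose from 25.9 ± 1.39 to 195 ± 14.8 FPKM and the small heat shock gene hspb1 fell from 34.05 ± 1.67 to 0.199 ± 0.139 FPKM. Adjusted over the list alone, the counts were the same; with median centring 11, 15, 9 and 12 genes rose and 12, 7, 4 and 12 fell.

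Skeletal muscle and epidermal genes fell, while the neural, neural crest and yolk lists were not called. Of 26 skeletal muscle genes, 26 fell, with a median log2 difference of -4.76 (camera adjusted p = 2.4e-07; adjusted p = 0.24 with an estimated correlation); muscle creatine kinase ckma went from 184 ± 4.25 to 2.11 ± 0.403 FPKM and the calcium pump gene atp2a1 from 116 ± 2.22 to 1.08 ± 0.0442 FPKM. Of 21 epidermal genes, 0 rose, 20 fell and 1 did not pass (camera adjusted p = 0.0012; adjusted p = 0.15 with an estimated correlation); the keratin genes krt8 and krt4 went from 714 ± 9.97 to 37.9 ± 5.46 FPKM and from 242 ± 1.58 to 41.2 ± 3.23 FPKM. Of 12 neural genes, 1 rose, 10 fell and 1 did not pass, and 2 rose and 10 fell adjusted over the list alone. The camera adjusted p of this list was 0.12, but 0.044 with a filter at 5 FPKM and 0.045 with no filter. With an estimated correlation the camera adjusted p was 0.38. The splicing factor gene nova2 fell from 18.9 ± 0.307 to 1.52 ± 0.206 FPKM. Of 8 neural crest and pharyngeal arch genes, 1 rose, 5 fell and 2 did not pass (camera adjusted p = 0.59); dlx5a fell from 3.75 ± 0.482 to 0.220 ± 0.0828 FPKM. Of 4 yolk and liver lipoprotein genes, 2 rose, 1 fell and 1 did not pass (camera adjusted p = 0.49, and 0.039 with no filter); the fallen gene, apoa1a, lost its call with quantile normalization (-0.08, limma adjusted p = 0.65). Both measured hatching gland genes fell, of which xbp1 went from 171 ± 0.861 to 75.1 ± 11.2 FPKM, while the call of agr2 ended with quantile normalization (-0.44, limma adjusted p = 0.17). No heart muscle gene reached the filter; gata6 read 0.601 ± 0.0894 and 0.122 ± 0.119 FPKM. With median centring 26 muscle and 18 epidermal genes fell, and the counts of the other lists adjusted over the list alone were the same as over all genes.

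Ribosomal protein genes fell almost throughout. Of 75 measured, 1 rose and 74 fell, the same adjusted over the list alone, with a median log2 difference of -3.49 (camera adjusted p = 7.6e-09; adjusted p = 0.68 with an estimated correlation). rpl13 went from 280 ± 16.9 to 2.62 ± 0.509 FPKM, rps3 from 93.2 ± 3.04 to 0.530 ± 0.187 FPKM and rps12 from 724 ± 48.8 to 32.4 ± 4.16 FPKM. With median centring 2 rose and 68 fell. In all, camera called 3 of 28 lists higher and 8 lower, some of which share genes, and none with an estimated correlation. Of the 10 splits of the 6 libraries into groups of 3, 3 gave at least as many list calls with the preset correlation, the real split included. The other splits mixed the groups unevenly and kept part of the real difference, so this count does not measure chance.

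**Figure D3:**
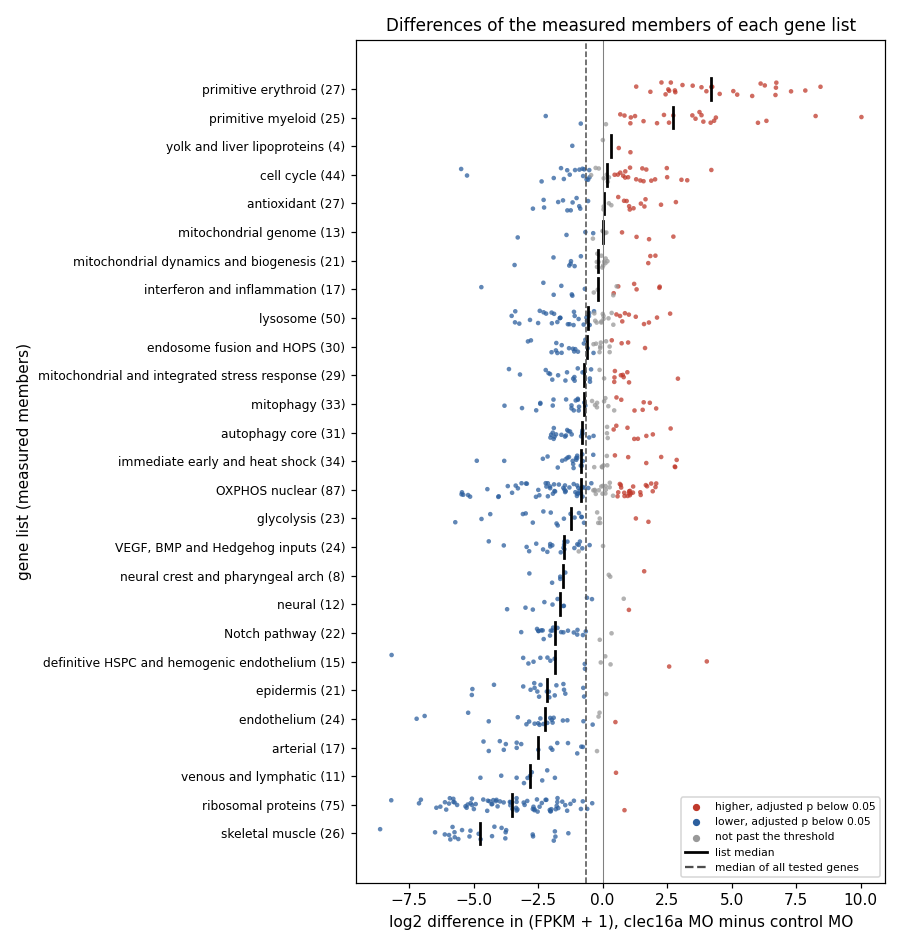
Each point is 1 measured member of the gene list on the y axis (a list whose result is not reported here is left out), placed by its log2 difference, clec16a MO minus control MO; red and blue members passed the threshold upward and downward, the black bar is the list median and the dashed line the median of all tested genes. The erythroid and myeloid medians lie at 4.21 and 2.74 and the skeletal muscle median at -4.76, against -0.66 for all genes.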

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

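The tests left out rows without a gene name. Of the 16 rows that carried a date in place of a gene name, 2 were higher in every clec16a MO library than in any control library. One read 8.40 ± 3.15 FPKM (SD, n = 3) in the clec16a MO libraries and 1.77 ± 0.219 FPKM in the control libraries, and the other 1.01, 2.02 and 3.17 FPKM where each control library was listed at 0. Another 10 of these rows were lower in every clec16a MO library and 4 did not separate the groups, while among the 12153 genes tested the groups did not overlap for 83.7%. The genes behind these rows were not identified, and no explanation was tested.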

How the results depend on the processing

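The 2 alternatives that left out or summed genes were chosen after seeing the data; the others were planned. The call and direction of clec16a held under all of them, with log2 differences from -1.46 to -0.63. Without each library in turn, the genes higher numbered 2941 to 3352 and the genes lower 6161 to 6798, with 3 lists higher and 8 to 9 lower. With no filter on low values 10430 genes were lower and 5 lists higher, and with a filter at 5 FPKM 3472 genes were lower; these alternatives test more or fewer genes. With an estimated correlation in camera 0 lists were higher and 0 lower, and 2 and 4 at an unadjusted p under 0.05. For the endothelial, arterial, and venous and lymphatic lists the estimate was below the preset 0.01 (-0.0086, -0.0032 and -0.015). Their calls therefore ended through the fewer degrees of freedom of that run, not through correlation. The lmo2 difference reversed to 0.62 with median centring and to 0.0059 without clec16a MO replicate 3 (-0.11 to 0.0059 without each library in turn), and etv2 reversed to 0.31 with median centring; the cause was not tested. Of 139 tested named genes, 132 kept their call and direction in every alternative run on them. Of 2192 values, 7 were weaker, 8 stronger and 3 reversed. Most named genes were picked for large differences or small p-values in these same libraries, so their stability was largely set in advance. Over all genes, 7871 of the 9877 calls kept call and direction with median centring and 108 were called the opposite way. With quantile normalization these counts were 7953 and 140. Deviations of samples that share a replicate number correlated by 0.044, -0.018 and 0.0054, and not every sample correlated best with its own number. These values show no pairing but cannot exclude it, since the control deviations were small and may be technical. With a replicate block 3239 genes were higher and 6604 lower, and 9678 calls were shared with the fit without it. Depth is unknown, so what it limits was not determined.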

Other observations

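All tests in this part, except the counts over other splits of the libraries, were chosen after the results were seen. Heme synthesis genes rose with the erythroid genes: of 10 measured, 9 rose and 1 fell (camera adjusted p = 6.1e-05 over 12 lists chosen after seeing the data; adjusted p = 0.091 with an estimated correlation). alas2, the erythroid form of the first enzyme of the pathway, went from 2.104 ± 0.444 to 326 ± 53.2 FPKM (SD, n = 3), while alas1, the form of other tissues, went from 37.0 ± 2.54 FPKM to 0.452, 0.619 and 0 FPKM. Of 10 genes of iron uptake and storage, 6 rose, 1 fell and 3 did not pass (camera adjusted p = 0.073, 0.029 with quantile normalization, and 0.28 with an estimated correlation). Of 20 collagen genes, 0 rose and 19 fell (camera adjusted p = 0.0011; adjusted p = 0.091 with an estimated correlation); col1a1a went from 20.6 ± 0.476 to 0.621 ± 0.406 FPKM and col4a1 from 6.35 ± 0.345 to 0.157 ± 0.140 FPKM. Of 9 tubulin genes 3 rose and 6 fell (camera adjusted p = 0.55), and of 11 HSP90 and co-chaperone genes 4 rose and 4 fell (camera adjusted p = 0.90). With median centring the heme synthesis counts were the same, and 1 collagen gene rose and 17 fell. Of the 7 protein complexes, the proteasome had 13 of 38 genes higher and 18 lower, the CCT chaperonin 0 and 6 of 8, eIF3 4 and 6 of 14, the COP9 signalosome 3 and 1 of 8, the RNA exosome 3 and 7 of 10, RNA polymerase II 6 and 3 of 11 and SF3 2 and 7 of 9. With median centring the proteasome turned to 19 higher and 14 lower, but with quantile normalization it counted 12 higher and 21 lower. The others, in the same order, counted 1 and 5, 5 and 6, 7 and 1, 3 and 5, 8 and 3, and 2 and 6 with median centring. None of these was called (camera adjusted p from 0.090 to 0.82). The CCT chaperonin passed with quantile normalization (camera adjusted p = 0.010), but with an estimated correlation its camera adjusted p was 0.92. Against random lists matched on level, the genes of the COP9 signalosome kept closest together (percentile 0.41, and 8.37 to 90.5 for the others).

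The ratio of neighbouring mitochondrial genes differed between the groups, and no cause of this was tested. The log2 ratio of mt-nd4l to mt-nd4 was 0.13 ± 0.12 (SD, n = 3) in the control libraries and -3.22 ± 0.65 in the clec16a MO libraries, and that of mt-atp8 to mt-atp6 was 0.38 ± 0.10 and 0.01 ± 0.12.

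Blood cell genes were higher, and endothelial, muscle and epidermal genes lower, in the clec16a MO libraries. A lower share of endothelial cells alone would raise the markers of every other cell type, and the skeletal muscle median of -4.76 argues against it as the whole cause. More blood cells that diluted all other cell types alike would lower muscle and epidermal genes by one factor, yet among genes at 10 FPKM or more in the control libraries the median log2 difference of 20 muscle genes minus that of 11 epidermal genes was -2.77 (95% interval over resampled genes -3.92 to -0.95; SD 0.31 over the clec16a MO libraries), which argues against this as the whole cause unless blood cells express some of these epidermal genes, of which krt8, cyt1 and cyt1l fell nearly as far as muscle genes (-4.21, -5.05 and -5.07). More blood cells beside other changes stays open, since the rise of blood genes is the pattern itself and does not test it. Exchanged group labels cannot be excluded by the clec16a difference of -1.32, because the kind of morpholino is not given and the sample titles do not name it, and an effect of the clec16a MO on cell numbers or on expression was not tested and stays open, as it cannot be told apart from any difference in collection or batch that followed the groups.

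Genes for subunits of one protein complex moved apart between the groups, though within the range of random lists matched on level (percentiles 0.41 to 90.5). Of 98 subunit genes of 7 complexes, 13 (13.3%, exact 95% interval 7.26% to 21.6%) lay more than 3 log2 units from their complex median. Among them were psmd3 in the proteasome and, named after their values were seen, cct2 and polr2h. cct2 has repeated rows and is uncertain, and polr2h rose from 4.81 to 127 FPKM. Paralogs were counted apart: the lowest and highest eIF3 genes, eif3ha (-3.95, among the 13) and eif3hb (2.37), are paralogs by name. The interval treats genes of a complex as independent, though the estimated correlation was 0.73 for the proteasome. Shallower clec16a MO libraries should leave abundant genes in place on average. Yet 10.9% of the 1520 genes at 50 FPKM or more in the control libraries fell 16-fold or more. That share covers all such genes, among them muscle, vessel and ribosomal protein genes. It does not single out the complex genes, so for their moving apart shallower libraries were not tested. A fall from reads moved between rows of one name would end on summing, yet 85.7% of 14 such rows still fell. Some of these rows share a name, as those of actc1a and cct2 do. Of the complex genes only cct2 is among them, so for the others this was not tested. Reads moved between paralogs of different names were not tested either. A different mix of cell types may be the cause, and the 13.3% leaves it open: the bound of 5% first set for it, and the 50% that replaced it after the result was seen, were both assumed, and how far subunit ratios differ between cell types was not measured. An effect of the clec16a MO on these genes was not tested and also stays open, as does a batch that followed the groups.

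Control libraries lay closer to one another than the clec16a MO libraries did. The median SD of log2 values was 0.0706 in the control and 0.261 in the clec16a MO libraries over genes at 1 FPKM or more in both groups, a ratio of 3.70. Counting noise in shallower libraries should fade in abundant genes. The ratio, 6.10 at 200 FPKM or more, does not test this, since such noise can fade in both groups alike. The clec16a MO spread itself was 0.190 at 50 FPKM or more and 0.195 at 200 FPKM or more. It did not fade between these levels, which argues against counting noise as the whole cause among such abundant genes. Control libraries made from one pool of cells or RNA could give as small a spread as theirs, 0.0319 at 200 FPKM or more. A small spread alone does not show it, and the labels do not say how replicates were made. A wider spread brought by the clec16a MO was not tested.

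Splits of the 6 libraries were too few to give a share under 0.05. Every other split also mixed the groups unevenly. Part of the real difference stayed between its groups, and the rest widened the spread within them. The counts below therefore do not measure chance, for genes or for lists. The real split gave 9877 genes past the threshold, 1 of 10 splits had as many, and the highest of the others gave 0 (limma, Benjamini-Hochberg). At an unadjusted p under 0.05 the real split gave 10006 genes and the others 4 to 9. For gene lists, 3 of the 10 splits, the real one included, gave at least the 11 of the real split, and the highest of the others gave 12.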
